A study of Arabidopsis thaliana with 10 samples.

How the data were processed

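Total RNA from roots was labelled with Cy3 from 50 ng by the Low Input Quick Amp kit, which primes on poly(A) tails, and hybridized to Agilent arrays, 1 array for each of the 10 groups of Col-0 and cycam. Per the file headers, the authors extracted the images with Agilent Feature Extraction 11.5.1.1 and protocol GE1_1105_Oct12, which gave a processed signal as an intensity, background-subtracted and detrended but not normalized between arrays. Per the file headers, the raw spot and local background signals are an intensity with no normalization. The flags deposited with each spot (well above background, saturated, outlier, control type) are in no physical unit (other) and hold 0, 1 or a control type code. The authors also deposited an intensity for each transcript, on a linear scale. Every column of it holds the same set of values, so that it was quantile normalized. The tool is not stated. Each column correlated best with its own array (r from 0.901 to 0.951 across genes).

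The processed signal was read for 61657 gene spots (59017 probes) per array, with 1319 control spots and all outlier spots left out. Spots of a probe were averaged, log2 values were taken relative to the 75th percentile of the array, and each locus was represented by its probe with the highest mean. A locus was tested when its probe lay well above background on at least 2 of the 10 arrays, which held for 24345 of 30529 loci and left out 6184. Coordinates are TAIR10 coding spans counted from 1. For the test of neighbouring genes, gene positions from the reference were used after the files were found to give one for only 74.3% of the genes. The Col-0 water array had 79.99% of probes well above background and the others 72.84% to 76.65%.

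The main model was an additive fit in limma 3.58.1 (R 4.3.3, data.table version 1.17.8) with 5 conditions and genotype over 10 arrays, which left 4 residual degrees of freedom. The prior degrees of freedom were 2.16 and the median residual SD was 0.169. Its contrasts were cycam minus Col-0, chitin minus water at 4 h, cellotriose minus water at 4 h, cellotriose minus chitin, and 8 h minus 4 h, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The fit assumes the same effect of a condition in both genotypes. The median half-width of the 95% interval was 0.261 for the genotypes, 0.412 against water, and 0.291 for the other contrasts. Comparisons of 1 array with 1 array, and the genotype difference of the 4 h responses, are values with no test, set beside the 45 pairs of arrays and 10000 random lists drawn within 20 expression bins. Where a gene was above background in 1 group only, its fold is given as a lower bound against the background level.

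Gene lists were tested by camera with a preset correlation of 0.01, and again with an estimated correlation, with adjustment over 32 lists, each with at least 4 measured members. There were 30 fixed lists and 2 lists read from the locus codes of the mitochondrial and chloroplast genomes, and 1 member whose symbol differed was left out. The fixed lists were early defence (early MAMP response), indole glucosinolate and camalexin synthesis, aliphatic glucosinolates, salicylic acid, jasmonate, ethylene, calcium signalling, reactive oxygen, nuclear mitochondrial stress, cell wall, xylem secondary wall, phenylpropanoid, oligosaccharide perception with the poly(A) ribonuclease, mRNA decay, root hair, iron, phosphate and nitrate, suberin, abscisic acid, auxin, morning clock, evening clock, shoot photosynthesis, cell cycle, heat shock, unfolded protein response, hypoxia, ER body, defensins and reference genes. These lists, the model and the rule for named genes were fixed before the data were examined. The rule took, per tested contrast, the 10 genes highest and the 10 lowest among named genes with an adjusted p under 0.05, a log2 difference of at least 1 and the same direction in every pair. Where none passed it took the 5 largest each way by the moderated statistic. It also took up to 4 members of each list with the largest change, the 10 largest each way per single array comparison, and always AHG2, CERK1, CORK1, PR1, WRKY33, AOX1A and the reference genes.

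The alternatives were normexp background correction (offset 50), quantile normalization, median scaling, the submitters' values, the mean over probes, a floor at the lowest signal well above background, no filter on dim probes, probes above background on all 10 arrays, the 4 h or the elicitor arrays only, each array left out in turn, slide as a block, and a trend in the variance. The 7 arrays of slide 1 alone, slide as a block for the lists, and the fits of genotype by elicitor and genotype by time on the 8 elicitor arrays (3 residual degrees of freedom) were chosen after the data were seen. The fits were tested on simulated data with 200 changed genes. At a log2 change of 1 they recovered 81.5% for the genotypes, 70% for the times, 70.5% for the elicitors, 0% for chitin against water and 0% for the interaction, and at a log2 change of 2 between 63% and 95.5%. For the elicitor and time contrasts the simulated change was the same in both genotypes. With changes simulated, up to 17 unchanged genes were called (elicitors, log2 change of 2). With no change simulated there were 0 calls in the 5 contrasts of the additive fit and 0 for genotype by elicitor. Correlations across arrays were tested with 100000 permutations. Figures were drawn with python 3.11.15 and matplotlib 3.10.9.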

Results

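Transcripts were measured in roots of 13-day-old Arabidopsis thaliana seedlings of 2 genotypes, both expressing the calcium reporter apoaequorin in the cytosol. Col-0 is the standard laboratory accession, and cycam is, by the series title, a mutant impaired in the rise of cytoplasmic calcium that follows cellotriose treatment. Roots were soaked in water, in 10 µM chitohexaose (an oligomer of N-acetylglucosamine, called chitin here) or in 10 µM cellotriose (an oligomer of glucose, a fragment of cellulose). The 10 arrays covered water, chitin and cellotriose at 4 h and chitin and cellotriose at 8 h in each genotype, with no water array at 8 h. Each array held labelled RNA pooled in equal amounts from 3 experiments, so that each of the 10 groups had 1 array and no replicate. The 75th percentile of the processed signal was 9043 on the Col-0 water array and 1151 to 2289 on the other 9 arrays. Between 72.84% and 79.99% of the 59017 gene probes lay well above background, and no gene spot was saturated. Values are log2 signals relative to the 75th percentile of the array, and the number of arrays limits the precision. Of 30529 loci, 24345 were bright enough to be tested.

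The comparison of cycam with Col-0 asked which root transcripts differ between the genotypes whatever the treatment, over 5 pairs of arrays. MRD1 (AT1G53480, chromosome 1, 19963476 to 19964712), a gene of unknown function, was 175-fold higher in cycam (log2 7.45, SE 0.27, adjusted p = 0.000328, higher in 5 of 5 pairs). QQS (AT3G30720, chromosome 3, 12349461 to 12349726), a regulator of starch content, was 11.6-fold higher in cycam (log2 3.54, SE 0.13, adjusted p = 0.000328), a value that rests on dim Col-0 signals, above background on 2 of 5 arrays. MAF5 (AT5G65080, chromosome 5, 25997650 to 26002211), a MADS-box repressor of flowering, was 7.14-fold higher (log2 2.84, SE 0.07, adjusted p = 0.000102). SGS3 (AT5G23570, chromosome 5, 7943621 to 7945874), a protein of RNA silencing, was 3.8-fold lower (log2 -1.93, SE 0.09, adjusted p = 0.000872).

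Further genes that were higher in cycam were the homeobox gene HDG4 (log2 2.80), the mitochondrial NADH dehydrogenase gene NDB4 (2.67), the DNA damage response gene NAC044 (2.44), SFH12 (2.29) and the uridine kinase gene UKL5 (2.26). Of the 5 Col-0 arrays, HDG4 and UKL5 were above background on 2, SFH12 on 1 and NDB4 on 3, so that the size of these differences depends on dim signals. The RNA-binding protein gene PUM9 was at least 6.62-fold higher and LCR30 at least 3.24-fold higher, since neither was above background in Col-0. Lower in cycam were the sterol desaturase gene CYP710A3 (log2 -2.31, above background on 2 of 5 cycam arrays, so that its size also depends on dim signals) and the plastid glyceraldehyde phosphate dehydrogenase gene GAPA-2 (-1.72). CRT1 (-1.40), the indole glucosinolate methyltransferase gene IGMT1 (-1.31) and VAMP721 (-1.21), which serves secretion, were lower too. The auxin response factor genes ARF21 and ARF20 and SRO4 were at least 1.84-fold, 2.26-fold and 1.71-fold lower. With normexp background correction their log2 differences were 0.24, 0.18 and 0.23. AHG2 (AT1G55870, chromosome 1, 20895663 to 20898359) encodes a poly(A)-specific ribonuclease that is known, though not from the labels, as the gene mutated in cycam. Its transcript differed by log2 -0.01 (SE 0.08, adjusted p = 0.952), which leaves the state of the protein unmeasured. The chitin receptor kinase gene CERK1 differed by -0.06 (adjusted p = 0.694), the cellooligomer receptor kinase gene CORK1 by -0.10 (0.564) and the early defence regulator WRKY33 by -0.23 (0.707).

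Of the 32 gene lists, 6 shifted between the genotypes. With an estimated correlation between the genes of a list the adjusted p was 0.946 for each of these 6 lists. All 15 measured nuclear genes of the mitochondrial stress response were higher in cycam (median log2 0.52, adjusted p = 1.48e-05), and 6 passed the test alone (12 adjusted over the list alone). Among these 6 were NDB4, UGT74E2 (1.37), GSTU24 (1.01) and UPOX (0.83). All 14 genes of phenylpropanoid and lignin synthesis were higher (median 0.34, adjusted p = 8.06e-05), with 3 past the test (9 adjusted over the list alone). These were the phenylalanine ammonia-lyase genes PAL4 (0.77), PAL1 (0.57) and PAL2 (0.55). All 14 genes of the abscisic acid response were higher (median 0.43, adjusted p = 8.06e-05), with 3 past the test (8 adjusted over the list alone). These were the phosphatase genes HAI2 (1.26) and HAI1 (0.76) and RD22 (0.64). All 11 genes of the suberin and Casparian strip list were higher (median 0.46, adjusted p = 0.00439), with 3 past the test (7 adjusted over the list alone). These were the suberin synthesis genes CYP86A1 (0.94), GPAT5 (0.66) and RWP1 (0.53), and RWP1 and RD22 were named after their values were seen. The transcripts of the mitochondrial genome were higher at 105 of 109 genes (median 0.33, adjusted p = 0.000399), with 1 past the test, ORF187 (0.72). This is an average over pairs that went both ways. The list median was lower in cycam in the chitin 4 h (-0.18) and chitin 8 h (-0.26) pairs. The jasmonate list was lower (median -0.17, adjusted p = 0.0138), with 6 of 26 genes higher. The only member past the test, AOC1, an enzyme of jasmonate synthesis, was higher (0.99). The mitochondrial genome list was not called without either water array (adjusted p = 0.112), and the jasmonate list was not called without either cellotriose 8 h array (0.0505) or with normexp background correction (0.0649).

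In lists that did not shift as a whole, single members passed in either direction. Higher in cycam were the nitrate transporter gene NRT2:1 (log2 1.29), nitrate reductase NIA1 (1.11) and nitrite reductase NIR1 (0.72), the pathogenesis gene PR5 (1.5) and the pipecolate synthesis gene ALD1 (1.49), the clock gene CCA1 (1.25), NAC103 (1.65), the heat shock gene HSP18.2 (1.91) and ERF71 (1.63). SPX1 (-0.68), of the phosphate and nitrate list, was lower, and was named after its value was seen. PR1 was too dim to be tested.

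By limma, 1802 of 24345 genes differed between the genotypes, 1293 higher and 509 lower in cycam. At least 2-fold differences were found at 365 higher and 54 lower genes. Each of the 1802 genes had the same direction in all 5 pairs. Since the genes were called on these same pairs, this is no separate support. With slide as a block 465 genes differed, of which 450 were among the 1802. Only the cellotriose 4 h pair lay on both slides, so that this fit equals leaving out 1 array of that pair and is no separate check. The 7 arrays of slide 1 alone gave 2 genes, MRD1 and AT3G28899, a setting chosen after the data were seen. The balance was 939 higher and 783 lower with the submitters' values, and 915 and 677 with quantile normalization. The count was 484 with normexp background correction and 645 with no filter on dim probes. Leaving out 1 array, which left 3 residual degrees of freedom, gave 673 genes without either water array, 671 without either chitin 4 h array, 465 without either cellotriose 4 h array, 538 without either chitin 8 h array and 372 without either cellotriose 8 h array.

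**Figure D1:**
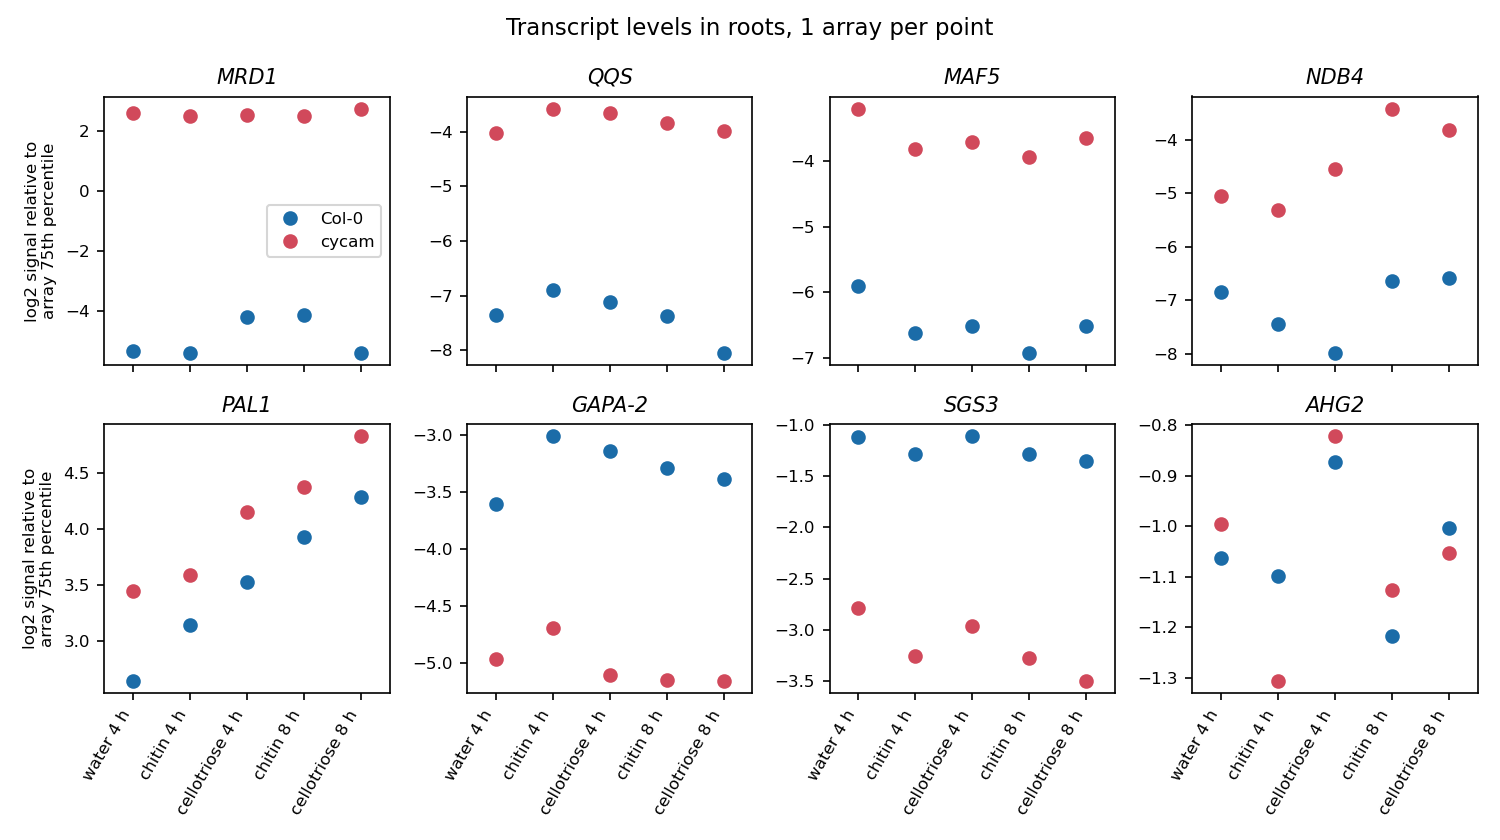
Transcript levels of 8 named genes in roots, as log2 signal relative to the 75th percentile of the array (vertical axis, own scale in each panel), against the 5 treatments, with 1 point per array of Col-0 (blue) or cycam (red) and no error bars. MRD1, QQS, MAF5, NDB4 and PAL1 lay higher in cycam in 5 of 5 pairs, GAPA-2 and SGS3 lay lower in 5 of 5, and AHG2 differed by log2 -0.01.

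The comparison of chitin with water at 4 h asked what chitin changes in roots of both genotypes, with 2 pairs of arrays. Genes of the iron deficiency response rose as a list (12 of 15 higher, median log2 0.34, adjusted p = 0.0126), with 0 genes past the test alone (3 adjusted over the list alone). With an estimated correlation the adjusted p was 0.945 for this and for the 2 lists that follow. The Col-0 water array stood apart from the other Col-0 arrays in the iron list (centred median -0.7393, next -0.183). Without it the iron list was still called (median 0.32, adjusted p = 0.000269). The reference genes, in which that array also stood apart, were 9 of 10 higher with chitin (median 0.22, adjusted p = 0.113). The largest members of the iron list were the ferric reductase gene FRO2 (2.42, SE 0.24, adjusted p = 0.355), the iron transporter gene IRT1 (2.38, SE 0.45, adjusted p = 0.65), CYP82C4 (2.15) and the coumarin synthesis gene S8H (2.07). Genes of the xylem secondary wall also rose as a list (10 of 11 higher, median 0.39, adjusted p = 0.0479), with the xylem proteases XCP1 at 0.69 and XCP2 at 0.62 and the laccase LAC17 at 0.52. Transcripts of the chloroplast genome rose as a list (91 of 113 higher, median 0.19, adjusted p = 0.0411). This rise was not shared by the genotypes. By single arrays the list median rose in Col-0 and fell in cycam (median difference of the response, cycam minus Col-0, -1.24). The early defence list did not pass in either direction, and WRKY33 was at 0.18 (SE 0.53, adjusted p = 0.941). The camalexin synthesis genes CYP71A12 (2.43, SE 1.08, adjusted p = 0.657) and CYP71A13 (2.40) were higher in both pairs without passing.

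No single gene differed between chitin and water by limma (0 genes, 1856 at an unadjusted p under 0.05 where 1217 were due by chance). The largest named genes by the moderated statistic, none of which passed, were FRO2, LBD31 (log2 0.91), PRE5 (0.74), the actin-binding profilin gene PRF4 (0.57) and IRT1 upwards. Downwards they were PAP28 (-0.73), the jasmonate methyltransferase gene JMT (-1.01), CYP81D1 (-0.69), MAPR2 (-0.68) and MAF5 (-0.66). In the self-test with 200 changed genes, this comparison recovered 0% at a log2 change of 1 and 87% at a log2 change of 2. Without the cycam water array the iron list had an adjusted p of 0.207 and the xylem list 0.687. The xylem list was reversed without the cycam chitin 4 h array (adjusted p = 0.856) and not called without a chitin 8 h array (0.0538) or a cellotriose 8 h array (0.071). The chloroplast list was reversed and called without the Col-0 water array (5.24e-06), reversed without the Col-0 chitin 4 h array (0.0905), and not called without a cellotriose 8 h array (0.0506), with quantile normalization (0.162) or with normexp (0.0893).

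The comparison of cellotriose with water at 4 h asked the same of the cellulose fragment. Genes of phenylpropanoid and lignin synthesis rose as a list (12 of 14 higher, median log2 0.27, adjusted p = 0.000714), with 0 past the test alone (5 adjusted over the list alone). With an estimated correlation the adjusted p was 0.774 for this list and for the 12 others of this comparison. PAL1 stood at 0.79 (SE 0.13, adjusted p = 0.221) and PAL2 at 0.73 (SE 0.12). Genes of indole glucosinolate and camalexin synthesis rose as a list (19 of 20 higher, median 0.32, adjusted p = 0.0269), with CYP71A12 at 2.54 and CYP71A13 at 2.54. This rise rested on Col-0, since the list median was -0.06 without the Col-0 cellotriose 4 h array. The ER body and beta-glucosidase list (10 of 10 higher, median 0.40, adjusted p = 0.027) and the aliphatic glucosinolate list (8 of 9 higher, median 0.27, adjusted p = 0.0272) rose too. In the ER body list the Col-0 water array stood apart (centred median -0.5565, next 0.082). Its median was 0.04 without that array and 0.06 with quantile normalization. The iron deficiency list (12 of 15 higher, median 0.45, adjusted p = 0.001, 0 past the test and 1 adjusted over the list alone) and the mRNA decay list (7 of 8 higher, median 0.28, adjusted p = 0.034) rose as well. Transcripts of the chloroplast genome (113 of 113 higher, median 0.42, adjusted p = 2.96e-08) and of the mitochondrial genome (102 of 109 higher, median 0.34, adjusted p = 4.4e-05) rose with them.

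Root hair, cell wall and xylem genes fell as lists with cellotriose at 4 h, with an adjusted p of 0.774 under an estimated correlation. The root hair list had 1 of 9 genes higher (median log2 -1.03, adjusted p = 0.001). In it the root hair regulator RSL4 stood at -1.25, the wall protein gene PRP1 at -1.65 and the expansin gene EXPA7 at -1.43. The xylem secondary wall list had 0 of 11 higher (median -0.47, adjusted p = 0.00276), with LAC17 at -0.96 and the cellulose synthase gene IRX1 at -0.69. The cell wall list had 5 of 19 higher (median -0.84, adjusted p = 0.027), and the jasmonate list 7 of 26 (median -0.16, adjusted p = 0.0323, 0 past the test and 1 adjusted over the list alone). Markers of shoot photosynthesis fell as well (4 of 16 higher, median -0.41, adjusted p = 0.000639, 6 adjusted over the list alone). The light-harvesting genes CAB2, LHCB2.1 and LHCB3 stood at -2.81, -2.20 and -2.04.

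No single gene passed for cellotriose against water by limma (0 genes, 3120 at an unadjusted p under 0.05 where 1217 were due by chance). The named genes largest by the moderated statistic, each with an adjusted p of 0.207, were the sinapate glucosyltransferase gene UGT84A1 (log2 1.75, SE 0.19), GSTF14 (1.38), PQL3 (at least 3.22-fold higher), PERK2 (2.11) and the gibberellin synthesis gene GA3OX2 (1.18) upwards. Downwards they were BBX28 (-2.01, SE 0.20), CYS2 (-0.97), the flavonoid repressor gene MYBL2 (-2.66), P1R3 (-1.08) and CAB2. Only the phenylpropanoid list was called whichever array was left out. Without the Col-0 water array the calls ended for indole glucosinolates (adjusted p = 0.0859), ER body (0.366), mRNA decay (0.129), jasmonate (0.103), cell wall (0.366), xylem (0.129) and root hair (0.0939). In that order their medians became 0.21, 0.04, 0.15, -0.25, -0.31, -0.33 and -0.45. The mitochondrial (0.602) and chloroplast (0.721) genome lists were reversed without this array. Without the cycam water array the calls ended for indole (0.0955) and aliphatic (0.402) glucosinolates, mRNA decay (0.0937), jasmonate (0.0937), iron (0.0799) and shoot photosynthesis (0.197). Without the Col-0 cellotriose 4 h array they ended for indole (0.884) and aliphatic (0.428) glucosinolates, ER body (0.142), mRNA decay (0.272), cell wall (0.0742) and iron (0.0742). In that order their medians became -0.06, 0.20, 0.41, 0.20, -0.92 and 0.45, so that ER body, cell wall and iron kept their size. Without the cycam cellotriose 4 h array, or with slide as a block, the calls ended for jasmonate (0.186), xylem (0.2) and the mitochondrial genome (0.0922). Normexp background correction ended the calls of indole (0.144) and aliphatic (0.128) glucosinolates, ER body (0.135) and mRNA decay (0.135). Quantile normalization ended those of indole (0.101) and aliphatic (0.0752) glucosinolates and ER body (0.802).

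Col-0 and cycam were also set side by side at 4 h, 1 array against 1, as values with no test. In Col-0 the root hair list had a median of -0.86 with chitin and -1.59 with cellotriose, and in cycam 0.74 and -0.59. The cell wall list had medians of -0.72 and -0.99 in Col-0 and 0.63 and -0.47 in cycam. The early defence list stood at -0.13 with chitin and 0.41 with cellotriose in Col-0, and at 0.39 and 0.02 in cycam. The indole glucosinolate list stood at 0.07 and 0.65 in Col-0 and at 0.34 and -0.01 in cycam. The calcium signalling list stood at -0.10 and 0.08 in Col-0 and 0.16 and -0.02 in cycam. Among single genes, CYP71A12 was 8.51-fold higher with chitin in cycam (log2 3.09) and at 3.68 with cellotriose in Col-0, where CYP82C2 (3.74) and CYP71A13 (3.72) were close to it. The transcription factor gene CBF4 was at least 18-fold higher with chitin and at least 21-fold with cellotriose in Col-0. The beta-amylase gene BAM5 was at least 35.2-fold lower with chitin and at least 16.5-fold lower with cellotriose in cycam. At least 2-fold differences from water were counted at 1832 genes for chitin and 1920 for cellotriose in Col-0, and at 781 and 792 in cycam, beside a median of 1693 over the 45 possible pairs of arrays. Across genes, which are not independent replicates, the responses of the genotypes correlated with r = -0.186 for chitin and r = 0.35 for cellotriose. The Col-0 water array was the brightest of the 10, and relative to it the brightest 1218 genes had a median of 0.49 in Col-0 chitin, 0.44 in Col-0 cellotriose and 0.48 in cycam water. With normexp the counts became 3290 and 3911 in Col-0 and 163 and 162 in cycam, and the correlations -0.537 for chitin and 0.365 for cellotriose.

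**Figure D2:**
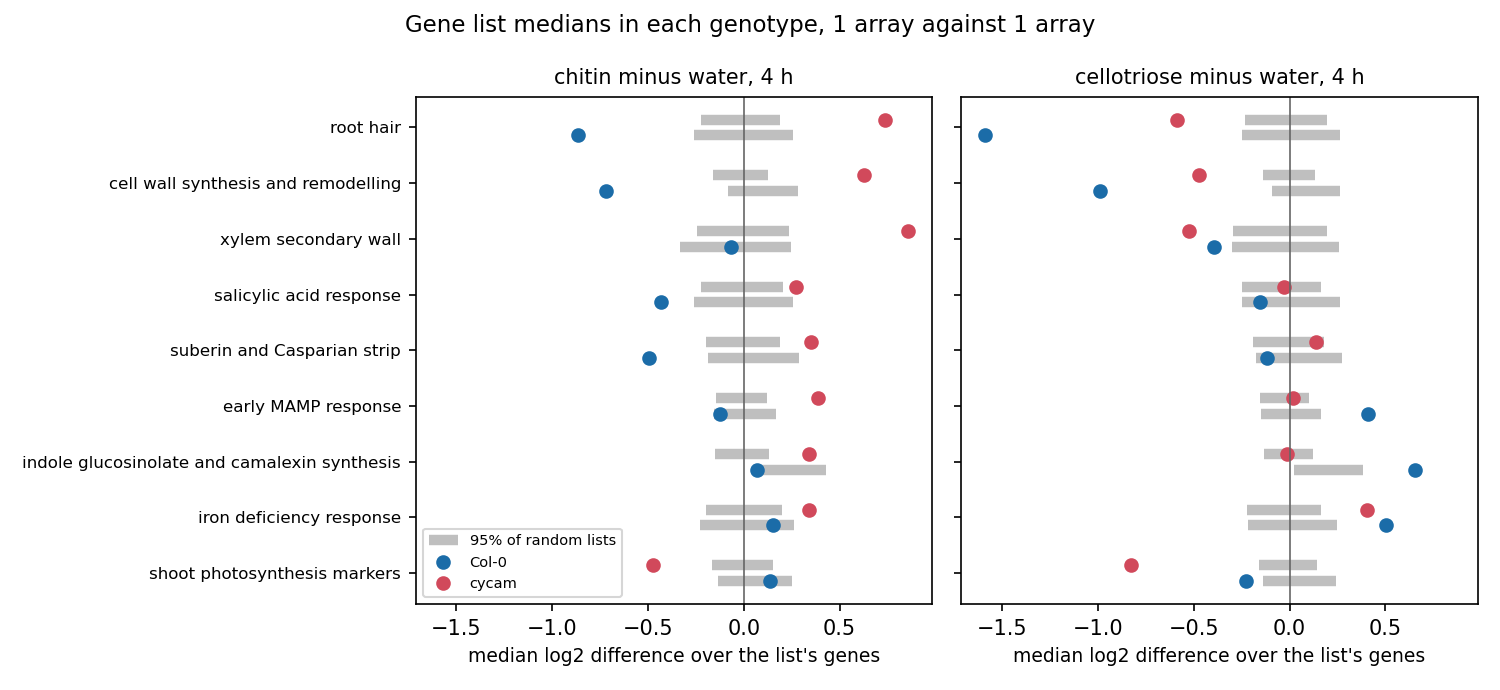
Median log2 difference from water at 4 h over the genes of 9 lists (horizontal axis), for chitin (left) and cellotriose (right), in Col-0 (blue) and cycam (red), each 1 array against 1; grey bars span 95% of random lists of the same size and expression. The bars do not allow for members of a list that move together, so that they are no test. With chitin the root hair list stood at -0.86 in Col-0 and 0.74 in cycam, and with cellotriose at -1.59 and -0.59.

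Cellotriose and chitin, given at the same dose and for the same times, differ in their sugar unit and in the length of the chain, and were compared in 4 pairs of arrays. Genes of the xylem secondary wall were lower with cellotriose (0 of 11 higher, median log2 -0.55, adjusted p = 1.41e-05), with 0 past the test alone (5 adjusted over the list alone). With an estimated correlation the adjusted p was 0.958 for this list and for the 6 others of this comparison. Among them LAC17 was at -0.97 (95% interval -1.55 to -0.38) and XCP1 at -0.87 (-1.41 to -0.34). Markers of shoot photosynthesis were lower (2 of 16 higher, median -0.41, adjusted p = 0.000582, 7 adjusted over the list alone), with LHCB3 at -1.21 (-1.91 to -0.51). The root hair list was lower (1 of 9 higher, median -0.68, adjusted p = 0.0101), with RSL4 at -0.87 (-1.66 to -0.08). The cell wall list was lower too (3 of 19 higher, median -0.45, adjusted p = 0.0175, 1 adjusted over the list alone), with the xyloglucan enzyme gene XTH25 at -1.06 (-1.57 to -0.55). The mitochondrial genome (96 of 109 higher, median 0.20, adjusted p = 0.00017), chloroplast genome (100 of 113, median 0.21, adjusted p = 0.000239) and mRNA decay lists (8 of 8, median 0.16, adjusted p = 0.022) were higher. For the 2 genome lists this held in cycam only. At 4 h and 8 h the mitochondrial medians were 0.67 and 0.45 in cycam and -0.06 and -0.29 in Col-0. The chloroplast medians were 0.47 and 0.57 in cycam and -0.02 and -0.22 in Col-0. The receptor kinase genes CERK1 (0.00, -0.21 to 0.21) and CORK1 (0.29, 0.03 to 0.56, adjusted p = 0.324) and the ribonuclease gene AHG2 (0.25, 0.05 to 0.45, adjusted p = 0.315) did not pass. The intervals of WRKY33 (0.02, -0.89 to 0.94), CYP71A13 (0.52, -1.33 to 2.38) and PROPEP3 (0.64, -1.12 to 2.40) reached close to or beyond a 2-fold difference in both directions.

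No single gene differed between cellotriose and chitin by limma (0 genes, 3455 at an unadjusted p under 0.05 where 1217 were due by chance), and for 87.2% of the genes the 95% interval lay within a 2-fold difference. Among the genes with a name, the largest by the moderated statistic, each with an adjusted p of 0.281 and the same direction in 4 of 4 pairs, were the receptor-like gene RLP30 (0.57, 0.38 to 0.76), UGT84A1 (1.0, 0.67 to 1.34), MYB56 (0.65), ALDH2C4 (0.52) and ERD9 (0.65) upwards. Downwards they were the meiosis gene SWI1 (at least 2.59-fold lower), CYS2 (-0.65), OFP3 (-0.99, -1.29 to -0.69), ASY1 (-0.61) and PRE5 (-0.63). The self-test recovered 70.5% of genes changed by log2 1 in this comparison. It moved both genotypes alike, so that this rate does not cover genes whose elicitor difference has opposite signs in Col-0 and cycam. The calls ended for the cell wall list without the cycam chitin 4 h array (0.162), the Col-0 cellotriose 4 h array (0.0565) or the cycam cellotriose 8 h array (0.0565). They ended for root hair without the Col-0 cellotriose 4 h array (0.0698) and for mRNA decay without the Col-0 cellotriose 4 h (0.189) or Col-0 chitin 8 h (0.0908) array. They ended for the mitochondrial genome without the cycam chitin 4 h (0.198) or cycam chitin 8 h (0.512) array and for the chloroplast genome without these (0.261 and 0.487) or the cycam cellotriose 8 h array (0.0727). With slide as a block they ended for cell wall (0.0565), mRNA decay (0.189) and root hair (0.0698), the same values as without the Col-0 cellotriose 4 h array.

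The difference between the elicitors was then compared between the genotypes on the 8 elicitor arrays, in a fit added after the data were seen. Of the genes that passed, 60 were higher with cellotriose than with chitin in Col-0 and lower in cycam at both times by the sign of single differences, some of them close to 0 in 1 genotype. Early defence genes were among the 60. CYP81F2, which modifies indole glucosinolates, stood at log2 1.78 at 4 h and 2.02 at 8 h in Col-0 and at -1.26 and -1.11 in cycam (double difference -3.08, SE 0.18, adjusted p = 0.0182). The transcription factor genes WRKY33 (-1.83, SE 0.16, adjusted p = 0.0291) and MYB51 (-2.76, SE 0.17, adjusted p = 0.0208), a regulator of indole glucosinolates, and the danger peptide gene PROPEP3 (-3.56, adjusted p = 0.0208) had the same pattern. So did the lipase gene GLIP1 (-4.50), NAC042 (-4.23), the iron deficiency gene CYP82C4 (-4.27), CYP82C2 (-4.66), the calmodulin-like gene TCH3 (-2.32) and the pipecolate hydroxylase gene FMO1 (-2.24). CYP71A12 (-3.70, adjusted p = 0.0557), CYP71A13 (-3.71, adjusted p = 0.0617) and PAD3 (-2.15, adjusted p = 0.0674) of camalexin synthesis did not pass. The named genes were chosen after their values were seen.

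By limma, 64 genes had such an interaction, 60 with a lower and 4 with a higher value in cycam (2713 at an unadjusted p under 0.05, 1217 due by chance), and 32 of the 64 have no name in the annotation. The 4 higher genes were AT1G54035 (2.92), AT1G26799 (3.11), AT5G29020 (2.32) and AT5G07260 (4.20, and -0.01 with the submitters' values). The indole glucosinolate list had a median double difference of -0.95 (0 of 20 positive, adjusted p = 5.84e-21, 3 members past the test) and the early defence list -0.80 (27 of 30 negative, adjusted p = 6.15e-18, 5 past the test). The calcium signalling list stood at -0.33 (20 of 25 negative, adjusted p = 0.000174, 1 past the test) and the salicylic acid list at -0.47 (15 of 17 negative, adjusted p = 0.000174). The adjusted p of these 4 lists was 0.203 with an estimated correlation. They were 4 of 14 lists called. Also negative were jasmonate (-0.26, adjusted p = 0.000459), ethylene (-0.27, 0.0142), reactive oxygen (-0.08, 0.0385) and mitochondrial stress (-0.26, 0.00851), with an adjusted p of 0.441 under an estimated correlation. So were cell wall (-0.64, adjusted p = 0.00851) and xylem (-0.69, 0.0036), with 0.571 as adjusted p under an estimated correlation. Root hair (-0.66, adjusted p = 0.0385, and 0.715 with an estimated correlation) and hypoxia (-0.43, adjusted p = 0.0265, and 0.493) were negative as well. With slide as a block the calls ended for ethylene (0.175), reactive oxygen (0.175), cell wall (-0.47, 0.0514) and root hair (0.175), and 10 lists were still called. The genome lists went the other way, with the mitochondrial genes at 0.74 (109 of 109 positive, adjusted p = 3.17e-35, and 0.218 with an estimated correlation) and the chloroplast genes at 0.62 (113 of 113, adjusted p = 4.36e-33, and 0.259). The count was 17 with slide as a block, 14 of them among the 64, and 258 with normexp, 43 of them shared. Of the 258, 105 were higher and 153 lower in cycam, a smaller excess of lower values than among the 64. It was 4 higher and 75 lower with the submitters' values. Leaving out an array gave 0 genes without the Col-0 chitin 4 h, Col-0 cellotriose 4 h, Col-0 chitin 8 h or cycam cellotriose 8 h array, 1 without cycam chitin 8 h, 2 without Col-0 cellotriose 8 h, 7 without cycam cellotriose 4 h and 11 without cycam chitin 4 h.

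**Figure D3:**
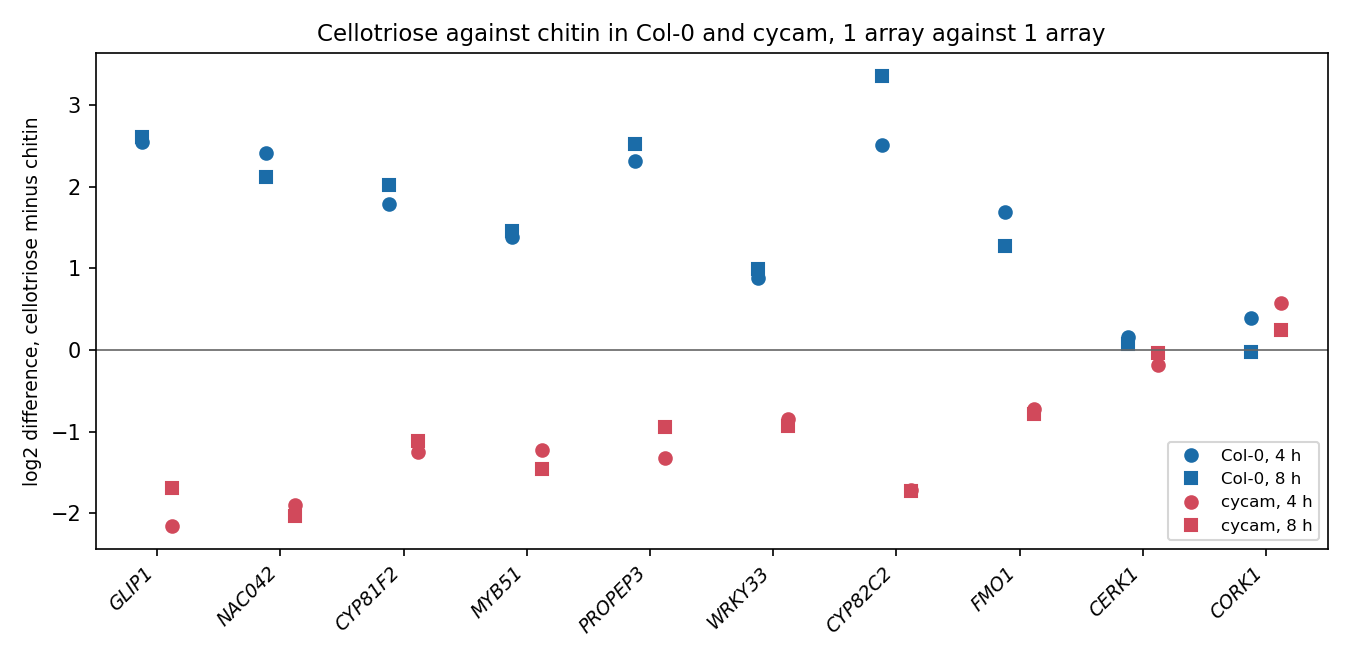
Log2 difference between cellotriose and chitin (vertical axis) for 10 named genes (horizontal axis), 1 array against 1, in Col-0 (blue) and cycam (red) at 4 h (circles) and 8 h (squares). CYP81F2 stood at 1.78 and 2.02 in Col-0 and at -1.26 and -1.11 in cycam, and the receptor kinase genes CERK1 and CORK1 lay closer to 0.

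The comparison of 8 h with 4 h asked what changes with time under the elicitors, in 4 pairs of arrays. Without a water array at 8 h, the time after treatment and the time of day were not separated. UGT84A1 (AT4G15480, chromosome 4, 8849000 to 8850472) was 4.02-fold higher (log2 2.01, SE 0.14, adjusted p = 0.0285). The flavonol glycosyltransferase genes UGT78D3 (1.90) and UGT78D1 (1.38) and the flavonoid hydroxylase gene TT7 (1.80) were also higher. MYBL2 (AT1G71030, chromosome 1, 26795383 to 26796226), a repressor of flavonoid synthesis, fell 5.15-fold (log2 -2.36, SE 0.22, adjusted p = 0.031). The nitrate transporter gene NRT2.4 (1.95), the sugar transporter gene SWEET13 (1.60), PQL3 (1.80), CYP78A9 (1.55), ERD9 (1.48) and ABCC15 (1.295) rose. The light-harvesting genes CAB2 (-2.32) and LHCA1 (-1.72), the anion channel gene SLAH1 (-2.13), the clock gene PRR7 (-1.82), CCL (-1.79), TPS8 (-1.79), HIS1-3 (-1.77), MEE14 (-1.56) and SNRK2-8 (-1.42) fell.

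Phenylpropanoid genes rose as a list from 4 h to 8 h (13 of 14 higher, median log2 0.36, adjusted p = 0.00013), with PAL2 (0.78) and PAL1 (0.75) past the test (7 adjusted over the list alone). With an estimated correlation the adjusted p lay between 0.859 and 0.896 for this list and the 13 others of this comparison. The nuclear mitochondrial stress list (13 of 15, median 0.38, adjusted p = 0.000393, 7 adjusted over the list alone) rose. So did the suberin list (10 of 11, median 0.46, adjusted p = 0.00415, 4 adjusted over the list alone) and the cell wall list (17 of 19, median 0.58, adjusted p = 0.00452, 1 adjusted over the list alone). The iron list rose (13 of 15, median 0.34, adjusted p = 0.00452, with bHLH38 at 1.16 past the test and 4 adjusted over the list alone). The cell cycle list (13 of 15, median 0.20, adjusted p = 0.00602) and the phosphate and nitrate list (9 of 11, median 0.36, adjusted p = 0.0109, 3 adjusted over the list alone) rose. The indole glucosinolate (17 of 20, median 0.36, adjusted p = 0.011), root hair (8 of 9, median 0.46, adjusted p = 0.016) and early defence lists (25 of 30, median 0.24, adjusted p = 0.037) rose as well. Markers of shoot photosynthesis fell (2 of 16 higher, median -0.66, adjusted p = 4.34e-07, 2 past the test and 12 adjusted over the list alone). The evening clock genes fell (2 of 9 higher, median -0.52, adjusted p = 0.000337, 6 adjusted over the list alone), of which PRR3 passed (-1.09). Transcripts of the chloroplast genome (1 of 113 higher, median -0.36, adjusted p = 6.46e-09) and mitochondrial genome (12 of 109 higher, median -0.32, adjusted p = 1.92e-06) fell.

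By limma, 153 genes differed between 8 h and 4 h, 77 higher and 76 lower at 8 h. At least 2-fold differences were found at 41 higher and 43 lower genes. The count was 30 with normexp, 96 with median scaling, 97 with the mean over probes, 258 with the submitters' values, 549 with probes above background on all 10 arrays and 947 with a trend in the variance. It was 0 with no filter on dim probes, with slide as a block or with the elicitor arrays only. Leaving out the cycam chitin 4 h array gave 1 gene, SPX3, and leaving out any other single array gave 0. The indole glucosinolate and early defence calls ended without the Col-0 chitin 4 h (0.296 and 0.472), cycam cellotriose 4 h (0.35 and 0.603), cycam chitin 8 h (0.224 and 0.67) or Col-0 cellotriose 8 h (0.196 and 0.196) array. The root hair call ended without the Col-0 chitin 4 h (0.103) or cycam chitin 8 h (0.0574) array. The phosphate and nitrate call ended without the Col-0 chitin 8 h (0.0721) or cycam cellotriose 8 h (0.0545) array. The cell cycle call ended without the cycam chitin 4 h (0.0831) or Col-0 cellotriose 4 h (0.0616) array or with slide as a block (0.0616).

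The medians of the mitochondrial and chloroplast genome lists went together over the 10 arrays (r = 0.9, permutation p = 0.00036, adjusted 0.00072, rho = 0.952, permutation p = 6e-05), 1 of 2 relations computed across arrays. The correlation was 0.93 without the cycam cellotriose 4 h and cycam water 4 h arrays, the farthest from the median, and 0.898 on slide 1, while slide 2 held only 3 arrays. The mitochondrial list was higher in cycam in the water (0.99), cellotriose 4 h (0.54) and cellotriose 8 h (0.49) pairs and lower in the chitin 4 h (-0.18) and chitin 8 h (-0.26) pairs.

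**Figure D4:**
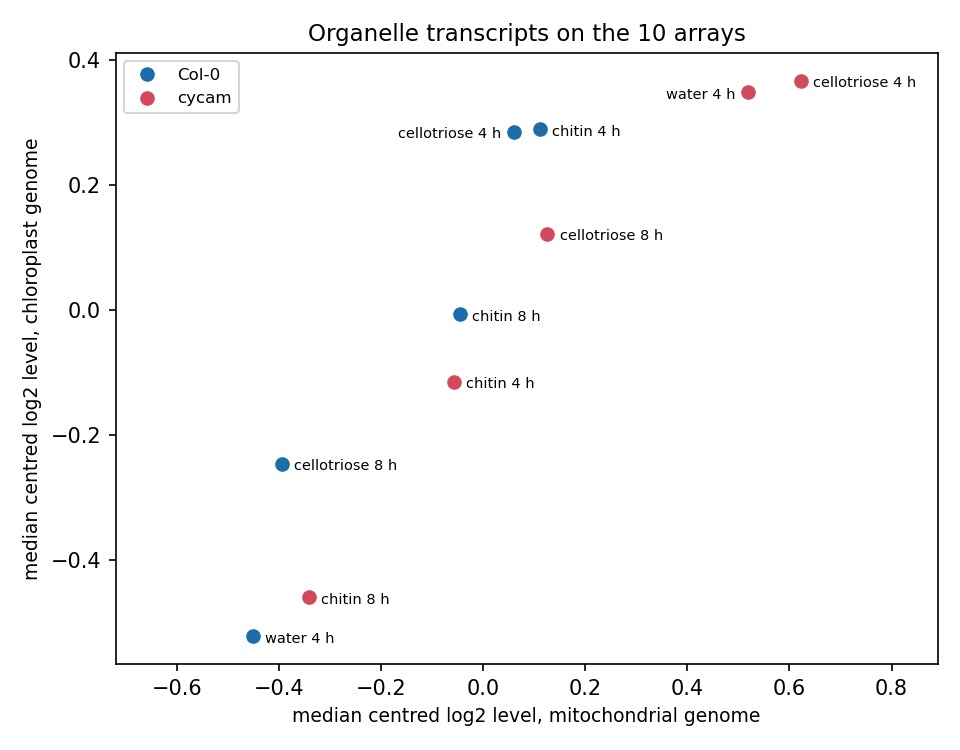
Median centred log2 level of mitochondrial genome transcripts (horizontal axis) against chloroplast genome transcripts (vertical axis), 1 labelled point per array, for Col-0 (blue) and cycam (red). Both lists varied together over the 10 arrays (r = 0.9).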

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

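The tests of the pseudogene share, of compression on the Col-0 water array, and of slide and other splits for the genotype-by-elicitor results were chosen only after the result was seen.

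The Col-0 water array lay apart from the other 9 arrays in its 75th percentile (9043) and in its share of probes well above background (79.99%). Among the 5 Col-0 arrays a single array lay apart in the centred medians of the salicylic acid list (chitin 4 h, -0.4942) and the calcium signalling list (cellotriose 8 h, 0.2008). The iron (-0.7393), ER body (-0.5565) and reference gene (-0.1604) lists lay apart on the Col-0 water array. Among the 5 cycam arrays the hypoxia list lay apart on the cellotriose 4 h array (-0.3167). By chance about 1 in 20 of the 66 groups examined would show such an array, and 8 did.

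In 8 lists the median response to chitin at 4 h had opposite signs in Col-0 and cycam, and both medians lay outside the range of 95% of random lists. Each response was 1 array against 1, and the differences were not tested. The random lists were drawn gene by gene, so that their range does not allow for members that move together. In these 8 lists the estimated correlation between members ran from 0.0572 (reactive oxygen) to 0.92 (chloroplast genome). Lying outside the range is therefore no evidence of a response. The median difference of the response, cycam minus Col-0, was 1.675 for root hair, 1.4379 for cell wall, 0.7659 for suberin and 0.6617 for salicylic acid. It was 0.4934 for heat shock, 0.1348 for reactive oxygen, -1.108 for the mitochondrial genome and -1.2443 for the chloroplast genome. At least 2-fold changes in opposite directions were seen at 211 genes for chitin and 84 for cellotriose, also not tested.

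The responses of Col-0 and cycam to chitin at 4 h did not go together, with r = -0.186 across genes (-0.537 with normexp), while r was 0.35 for cellotriose (0.365). Whether the slide of the cycam cellotriose 4 h array bears on the cellotriose value was not tested. The arrays behind the chitin value all lie on slide 1 and do not include that array, so that its slide could not affect the chitin value. After quantile normalization, which removes a trend with intensity, r for chitin was -0.17, against a compression of bright signals on the Col-0 water array. The brighter Col-0 water array cannot be told apart from the genotype, since cellotriose minus chitin, which leaves out water, correlated with r = 0.261, between the bounds set for either outcome, and with r = 0.421 under normexp, above the bound set for that array. A difference in root zone also stays open, since the root hair and cell cycle list means correlated with r = 0.03 over the 10 arrays, with an interval from -0.611 to 0.647 that holds both bounds set for it (permutation p = 0.934), and a difference between the genotypes stays open, untested.

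Over 4-fold differences between the genotypes, in all 5 pairs, were found at 71 genes higher and 3 lower in cycam. For the higher genes, the other probes moved with the chosen probe (median ratio 0.863, 95% interval 0.737 to 0.951). In 57 of 58 genes the mean of the other probes had the same direction, so that the differences did not rest on 1 probe. The test decides nothing on a probe mismatch here. The probes were designed on TAIR10, the Col-0 sequence, and a mismatch would lower the cycam signal. For the 3 lower genes the ratio was 0.789 (95% interval 0.541 to 0.969, 3 of 3 in the same direction). This interval lay above the bound of 0.5, but 3 genes fall under the minimum of 5 applied, so that a mismatch cannot be told apart there. Of the 74 genes, 8 had another of them within 100 kb, against a median of 10 in random sets and an upper limit of 18. This argues against clusters within 100 kb. Longer linked segments were not tested, and several of the genes lie on chromosome 3 between AT3G28510 (from 10685656) and LCR30 (from 15402413). Expression of pseudogenes in cycam is a candidate explanation for part of the higher genes, since 23.9% of the 71 were pseudogenes, against a median of 8.5% in random sets matched on expression (2.8% to 15.5%); with transcribed pseudogenes left out, the definition used first, it was 21.1% against 4.2%. The other 52 protein-coding genes are not covered by it, and other differences between the lines stay open, untested.

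In 64 genes, and in the indole glucosinolate and early defence lists, the difference between cellotriose and chitin was unequal in Col-0 and cycam, by the test of the difference itself, which does not test for opposite directions (adjusted p of 0.203 for both lists with an estimated correlation). For the 64 genes, the splits with the design as covariates gave a real value of 64 and a highest other of 0 (1 of 32 splits that could be fitted, out of 35). With slide added the values were 17 and 0. Most of the other splits overlap the covariates and leave the interaction in the spread, so that a count of 0 in them does not exclude chance. The splits first run without the covariates did not exclude it either (0 for the real split, 407 for the genotype split). Of the 8 single arrays left out, 4 ended the count at 0. For the lists chance cannot be excluded, since 3 of 35 splits gave an indole glucosinolate median as large (real -0.4734, highest other 0.6053) and 2 of 35 an early defence median as large (real -0.401, highest other 0.4326). Slide as the whole cause of the list pattern is argued against by pairs within a slide, since the indole list in cycam minus Col-0 stood at -0.8716 in the cellotriose 8 h pair and 0.27 in the chitin 4 h pair on slide 1, and 0.39 in the chitin 8 h pair on slide 2. A response of cycam that differs by elicitor is consistent with the 64 genes, as a hypothesis found and tested on the same data.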

How the results depend on the processing

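The fits of genotype by elicitor and genotype by time, the 7 arrays of slide 1 alone and the slide block for lists were chosen only after the result was seen.

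Of the called lists, 132 of 194 values under alternatives other than leaving out an array kept their direction and their side of the threshold and 62 fell short of it. Of 430 values with an array left out, 366 kept both, 59 fell short and 5 were reversed. The named genes kept both in 1717 of 2058 values, fell short in 321, newly passed in 15 and were reversed in 5. With an array left out they kept both in 1225 of 1972, fell short in 745 and newly passed in 2. Signal over background limited the dim genes, since 6184 loci were not tested.

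With normexp background correction, which moved the median of all genes by up to 0.13 (cellotriose minus water), 484 genes differed between the genotypes, 30 between 8 h and 4 h and 258 by genotype and elicitor. ARF21 (0.2386), ARF20 (0.1802), SRO4 (0.2309) and AT3G20395 (0.0934) were reversed. With the submitters' values AT5G07260 was reversed in the genotype-by-elicitor fit (-0.0064). The counts of at least 2-fold differences became 3290 (Col-0 chitin against water), 163 (cycam chitin), 3911 (Col-0 cellotriose) and 162 (cycam cellotriose). For the genotype pairs they became 4827 (water), 487 (chitin 4 h), 338 (cellotriose 4 h), 253 (chitin 8 h) and 396 (cellotriose 8 h). For 8 h against 4 h they became 475 (Col-0 chitin), 293 (cycam chitin), 423 (Col-0 cellotriose) and 130 (cycam cellotriose). For the response differences they became 5607 (chitin) and 3693 (cellotriose). The correlation of the responses between the genotypes became -0.537 (chitin) and 0.365 (cellotriose), and that of cellotriose minus chitin 0.421. With probes well above background on all arrays of the comparison, which tests fewer genes, they became 462 (cycam chitin against water), 440 (cycam cellotriose). On the same probes they were 1115, 775, 679 and 864 (genotype pairs with chitin 4 h, cellotriose 4 h, chitin 8 h and cellotriose 8 h), 629 and 431 (8 h against 4 h with chitin and cellotriose in cycam) and 1150 (cellotriose response difference). Probes above background on all 10 arrays gave 549 genes for the times, median scaling 96, the mean over probes 97, the submitters' values 258 (and 1 for cellotriose against water), and a trend in the variance 947. With no filter on dim probes 645 genes differed between the genotypes and 0 between the times, with the elicitor arrays only 0 between the times, and with slide 1 alone 2 between the genotypes. Slide as a block gave 465 (genotypes), 0 (times) and 17 (genotype by elicitor), and changed the number of called lists from 3 to 5 (chitin against water) and from 7 to 4 (cellotriose against chitin), while slide 1 alone gave 10 for chitin against water. With an estimated correlation 0 lists were called in each of the 5 contrasts. Only the cellotriose 4 h pair lay on both slides. In the additive fit, slide as a block therefore gave the same values as leaving out 1 array of that pair. The cause of the other changes was not tested, except that slide 1 alone and each left-out array fit fewer arrays.

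Leaving out 1 array gave 372 to 673 genes for the genotypes, 0 to 1 for the times and 0 to 11 for genotype by elicitor. It gave 5 to 11, 1 to 13, 6 to 17, 4 to 15 and 11 to 16 called lists for the genotypes, chitin against water, cellotriose against water, cellotriose against chitin and the times. Where an array was left out, its partner in the same condition was assumed to vary like the other groups. The chloroplast genome list with chitin was reversed without the Col-0 water array (adjusted p = 5.24e-06) and without the Col-0 chitin 4 h array (0.0905), in a range of 1.1e-17 to 0.0905. Xylem with chitin was reversed without the cycam chitin 4 h array (0.856, range 7.15e-08 to 0.856). Without the Col-0 water array the mitochondrial (0.602, range 3.56e-13 to 0.602) and chloroplast (0.721, range 6.69e-22 to 0.721) genome lists with cellotriose were reversed.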

Other observations

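The test of other splits for the genotype count was planned, while the covariates and the slide term in the splits for the elicitor and time counts, both tests of a mitochondrial lesion in cycam and that of shared organelle yield were chosen only after the result was seen.

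The lists that follow were not called in cycam minus Col-0. The early defence list had a median log2 of -0.09 (adjusted p = 0.111), indole glucosinolates -0.16 (0.0688), aliphatic glucosinolates -0.05 (0.434) and defensins -0.08 (0.73). The salicylic acid list had a median of 0.35 (adjusted p = 0.192) with 3 members past the test, PR5, ALD1 and GRX480 (0.62). The auxin list had 0.29 (0.0688) with 2 past it, GH3.3 (0.66) and GH3.1 (0.45), which conjugate auxin (4 adjusted over the list alone). The ethylene list (median 0.11, adjusted p = 0.945) held ACS7 (0.56) and HCHIB (0.43) higher and ACO1 (-0.70) lower, and calcium signalling (0.01, 0.793) held CML37 higher (0.98). The test pointed down in both, against the sign of the median. It also pointed down for reactive oxygen (0.03, 0.785) and root hair (0.06, 0.793).

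The iron list stood at 0.18 (adjusted p = 0.339), with NAS4 (0.96), bHLH38 (0.72) and OPT3 (0.70) higher and MYB10 lower (-0.38). The phosphate and nitrate list stood at 0.34 (0.473), with 4 members higher and SPX1 lower (-0.68). MYB10 and SPX1 were named after their values were seen. Cell wall stood at 0.11 (0.782) with the expansin gene EXPA1 higher (0.80), xylem at 0.04 (0.785), the cell cycle at -0.02 (0.192), shoot photosynthesis at -0.09 (0.21) and the ER body list at 0.00 (0.162). The morning clock list stood at 0.19 (0.215) and the evening clock list at -0.02 (0.282), with BOA lower (-0.72). Heat shock (0.07, 0.785) and the unfolded protein response (0.02, 0.97) were not called. Nor were hypoxia (-0.25, 0.177, with the cysteine oxidase gene PCO2 at -0.68 and ERF71 at 1.63) and oligosaccharide perception (-0.03, 0.555). The same held for mRNA decay (adjusted p = 0.785), reference genes (0.00, 0.758) and the chloroplast genome (0.10, 0.853). Genotype by time, fitted on the 8 elicitor arrays, gave 0 genes by limma (504 at an unadjusted p under 0.05, 1217 due by chance). Of its lists, 6 were called, each with an adjusted p of 0.993 under an estimated correlation. The suberin list had a negative double difference (0 of 11 positive, median -0.35, adjusted p = 5.06e-05), since its rise from 4 h to 8 h was smaller in cycam (0.06 with chitin and 0.10 with cellotriose) than in Col-0 (0.65 and 0.60). The cell wall (-0.30, adjusted p = 0.0162), root hair (-0.45, 0.01) and ER body lists (-0.22, 0.0213) were negative too, and the iron list (0.28, 0.01) and chloroplast genome (0.12, 0.0213) positive.

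In other splits of the 10 arrays with condition as a block, the genotype count had a real value of 1802 and a highest other of 1 (1 of 100 splits). Most of these splits keep some pairs together and leave part of the genotype difference in the spread, so that low counts in them say little. Of the 16 splits that part all 5 pairs, only the real one gave as many genes, and the highest other was 0. So few splits cannot exclude chance. For 8 h against 4 h, fitted with genotype and elicitor on the 8 elicitor arrays, the real value was 121 and the highest other 0 (1 of 33 splits). With slide added to this fit the real value was 69 and the highest other 0. Most of the other splits keep matched arrays together and leave the time difference in the spread, so that a count of 0 in them does not exclude chance. Without the covariates, as first run and planned, chance was not excluded either, since the real count was 1 and the genotype split gave 407. The fit over 10 arrays with slide as a block gave 0 genes for 8 h against 4 h, and a fit with each condition as its own term on the 8 arrays also gave 0. For cellotriose against chitin the splits decide nothing and chance cannot be told apart, since a real value of 0 is reached by every split (33 of 33 splits, highest other 34).

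A poly(A) lesion in mitochondria may raise mitochondrial transcripts in cycam, as a hypothesis, for which the tables give no more than the sign of 5 pairs. Mitochondrial genes were higher in cycam in 3 of 5 pairs and lower in 2. By the rule written for this comparison, at least 2 pairs each way, that outcome counts against the hypothesis. It was left undecided only because both organelles correlated with r = 0.9 over the 10 arrays. In the 2 pairs where mitochondrial genes were lower (chitin 4 h -0.18, chitin 8 h -0.26), chloroplast genes were lower by more (-0.39 and -0.45). Organelle RNA yield shared by both organelles is a candidate explanation for that correlation. Relative to the chloroplast, the mitochondrial difference was higher in 5 of 5 pairs (0.14, 0.20, 0.48, 0.19 and 0.12), as the hypothesis needs. With 5 pairs no sign test can give a p under 0.0625, and a lower chloroplast level in cycam would give the same sign. The lesion therefore stays an undecided hypothesis, with the count of mitochondrial pairs alone against it.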
